A study of Mus musculus with 10 samples.

How the data were processed

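Chromatin was recovered on streptavidin from HT22 cells expressing BirA alone or BirA with FLBIO-tagged Klf9, and sequenced. The labels give 4 pulldown libraries and 1 input library for each line. Per the labels' protocols, cells were fixed with paraformaldehyde and a protein crosslinker, lysed in SDS buffer and sheared by sonication. CASAVA, FastQC, Bowtie and bedtools and the genome build mm8 are named in the submitters' processing notes, with no versions, roles or order. The peak caller, its thresholds, the treatment of replicates and the way in which the input and BirA-only libraries entered are not given in the sources used here. No values per library were analysed here.

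The deposited file is one list for the whole series. Per the file headers its columns are chromosome, start and end. The listed values are other than counts or signal: whole-number positions in base pairs, as deposited by the authors, with no score, fold or p-value. The positions were read as 1-based and inclusive, because 2230 starts lay at a multiple of 340 plus 1 and 2324 ends at a multiple of 340. Width was computed accordingly, as end minus start plus 1. A region with both boundaries on this grid of 340 bp then has a width that is a multiple of 340 bp by arithmetic. Reading them as 0-based, with the end excluded, shortens each region by 1 bp.

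A RefSeq gene table of GRCm38, another build than that of the list, was available. It gives gene extents without strand. Before it was used, the builds were compared. With the positions taken as deposited, 310 region midpoints (8.82%) lay within 1 kb of a protein-coding gene boundary, more than at 13 of 14 shifts of 20 kb to 2 Mb in either direction, which gave between 153 and 316, so this check alone did not separate the builds. A scan of shifts up to 5 Mb by chromosome, added after the data were seen, gave the highest count away from 0 on 19 of 20 chromosomes, the exception being chromosome 19. In the list 9 regions on 5 chromosomes ended past the last gene of that chromosome in the GRCm38 table. A chromosome can extend past its last gene, so this count does not separate the builds. Because of the scan and the build named in the processing notes, the positions were not treated as GRCm38 positions. No coordinate was converted and no region was assigned to a gene. The table was used to count genes per chromosome (21887 protein-coding genes and 49943 genes of all types on chromosomes 1 to 19, X and Y) and in the comparison of builds. It also gave the far end of each chromosome in random placement, at the last gene or region. The same end, which rests largely on another build, served as chromosome length in densities per Mb and in the alternative by length. The analyses planned before the data were examined that need a matching genome were not run: the share of regions at promoters, GC, CpG and motif content, and the test of 14 fixed gene lists.

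Chromosome counts were compared with the expectation from protein-coding genes by a chi-square statistic and 100000 multinomial draws, and each chromosome by a 2-sided exact binomial test with exact (Clopper-Pearson) 95% intervals and Benjamini-Hochberg adjustment over the 21 chromosomes at 0.05. Proximity was the number of regions with another within 10 kb, edge to edge, compared with 1000 random placements of the same widths on the same chromosomes, from 3 Mb (or the first region) to the last gene or region; the test was one-sided, a permutation test by random placement. Regions were linked into groups where successive gaps were at most 10 kb. Counts in windows of 1 Mb were compared with 1000 placements.

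The regions named in the text followed a rule fixed before the data were examined for the case of differing builds: the 10 widest regions and the 5 groups with the most regions, ties in genomic order. Alternatives fixed at the same time were merging of regions, autosomes only, the wider regions of the list (at least the median of 901 bp, in place of a stricter score, as none is listed), other reference distributions for chromosomes, other distances and other placements. Joining regions less than 340 bp apart, leaving out regions under 100 bp, leaving out chromosome Y or 1465 olfactory and vomeronasal receptor genes, the 0-based reading, placement of each region within its own 1 Mb window and the windows of 1 Mb were added after the data were seen.

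The tests were tested on simulated data with 3516 regions. With no chromosome changed, 0 of 420 chromosome tests in 20 simulated lists passed, and a chromosome 11 raised 1.5-fold was called in 20 of 20. Random placements were called clustered in 1 of 20 lists, and lists with 200 regions moved next to others in 20 of 20. These lists were placed uniformly along chromosomes, as the test assumes, so density that varies along a chromosome was not simulated. The chromosome and clustering simulations used fewer draws and placements than the tests of the list. A constant shift against gene boundaries was recovered on 5 of 5 simulated chromosomes with 30% of midpoints on boundaries. That setting was easier than the list on most chromosomes. In the list the share at the best shift ranged from 13.6% on chromosome 5 to 39.9% on chromosome 11. The shifts found on chromosomes 1, 4, 8, 10, 12, 14 and X lay beyond those simulated. Regardless of sign, the smallest of them was 502 kb on chromosome 4 and the largest -2889.5 kb on chromosome 8. Shifts that change along a chromosome were not simulated. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. The intervals cover counting error over regions only; sequencing depth per library is unknown, and error between replicates and in the calling of regions is not included.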

Results

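The study mapped where the transcription factor Klf9 associates with chromatin in HT22 cells, an immortalised mouse hippocampal neuronal line. Klf9 is a member of the Krüppel-like factor family, zinc-finger proteins that bind GC-rich DNA. The factor carried an FLBIO tag and was expressed together with BirA, a bacterial enzyme that attaches biotin to an acceptor peptide, so that tagged Klf9 and its DNA could be recovered on streptavidin. Cells with BirA alone served as the control line. Each of the 2 lines gave 1 input library and 4 pulldown libraries, 10 libraries in all. The result is a single list of regions for the whole series, with a chromosome, a first base and a last base per region and no height, fold or p-value. Library depths, replicate values and the signal in the BirA-only control are therefore unknown here, and none of the values below has a replicate error. No comparison of the tagged line with the control line could be computed. Positions are given as deposited, on the build mm8 per the submitters' processing notes. No genome sequence or annotation of that build was used, so regions are identified by position and no gene, exon or promoter is assigned to them.

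The list held 3516 regions, which together covered 3.10 Mb and lay on 20 chromosomes, the 19 autosomes and chromosome X. The median width was 901 bp (95% interval of the median 889 to 919 bp, from binomial order statistics), with quartiles at 680 and 1020 bp and a mean of 882 ± 301 bp (SD over regions). No 2 regions overlapped and no line was repeated. Widths were concentrated at a few exact values, since 667 regions (19.0%) measured 680 bp, 603 (17.2%) measured 1020 bp, 172 (4.89%) measured 1360 bp and 24 measured 1700 bp, all multiples of 340 bp. At the lower end, 155 regions were narrower than 340 bp, 40 were narrower than 100 bp and 3 consisted of 1 bp.

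**Figure D1:**
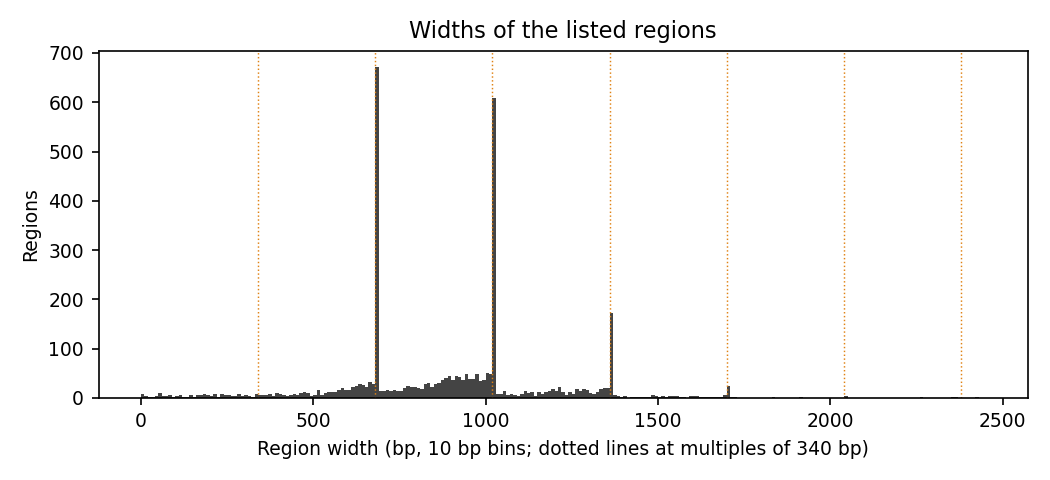
Histogram of region widths in bp (10 bp bins, x axis) against the number of regions (y axis), with dotted lines at multiples of 340 bp. The tall bars are the 667 regions of 680 bp, the 603 of 1020 bp and the 172 of 1360 bp.

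The widest region, of 2429 bp, lay on chromosome 7 from 15470292 to 15472720. It was followed by regions of 2360 bp on chromosome 15 (78753861 to 78756220), 2359 bp on chromosome 15 (76033202 to 76035560) and 2269 bp on chromosome 17 (26442522 to 26444790). Regions of 2040 bp were listed on chromosome 4 (150838621 to 150840660), chromosome 7 (109912481 to 109914520) and chromosome 15 (76303821 to 76305860). The remaining members of the 10 widest were 1919 bp on chromosome 11 (93701732 to 93703650), 1831 bp on chromosome 11 (120164501 to 120166331) and 1830 bp on chromosome 5 (3808122 to 3809951). Chromosome 15 held 3 of these 10 regions, and chromosomes 7 and 11 held 2 each. Of the 10, 4 stood within 1 kb of another listed region. The gap was 10 bp for the region at 76033202 on chromosome 15 and for both regions on chromosome 11, and 971 bp for the widest region.

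The listed regions were spread unevenly over the chromosomes. Chromosome 11 held the most, 401 regions or 11.4% of the list, against 7.35% of the protein-coding genes, a ratio of observed to expected regions of 1.55 (95% interval 1.41 to 1.70). Chromosome 15 was also above its share of genes, with 215 regions and a ratio of 1.72 (1.51 to 1.96), as was chromosome 19, with 182 regions and a ratio of 1.61 (1.39 to 1.85). Chromosome X held 27 regions where its share of genes gave 155, a ratio of 0.174 (0.115 to 0.253), and no region was listed on chromosome Y, where 41.1 were expected. The expectation for chromosome Y comes from its 256 protein-coding genes in the GRCm38 table. Whether it holds for the build of the list was not examined. Among autosomes the deficit was deepest on chromosome 14, with 68 regions and a ratio of 0.497 (0.387 to 0.629), and on chromosome 13, with 82 regions and a ratio of 0.616 (0.491 to 0.762).

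The list averaged 16.1 regions per 100 protein-coding genes, from 27.7 on chromosome 15, 25.8 on chromosome 19 and 24.9 on chromosome 11 down to 7.99 on chromosome 14 and 2.80 on chromosome X. The distribution differed from that of protein-coding genes (chi-square 531, 20 degrees of freedom, Monte Carlo p = 1e-05, the smallest that 100000 draws can give). Of the 21 chromosomes, 9 were above and 10 below expectation by 2-sided exact binomial tests with Benjamini-Hochberg adjustment over the 21, and the adjusted p was 6.97e-17 for chromosome 11 and 2.06e-36 for chromosome X. Chromosomes 9 and 18 did not pass, at ratios of 1.01 and 0.889. The 10 below included chromosome Y. With chromosome Y left out, the chi-square was 483, 17 chromosomes passed and chromosome 8 lost its call. These tests and intervals cover counting error only and treat regions as independent. With regions within 10 kb of each other counted once, 14 chromosomes passed, and chromosomes 1, 3, 6, 12 and 16 no longer did. Without olfactory and vomeronasal receptor genes, chromosomes 3, 4, 7 and 8 lost their calls, which left 6 chromosomes above and 9 below, and on autosomes alone chromosomes 3, 4 and 8 lost theirs. When length replaced gene number, the ratio on chromosome 7 reversed to 1.44, past the threshold, and that on chromosome 3 fell to 0.901 and did not pass.

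**Figure D2:**
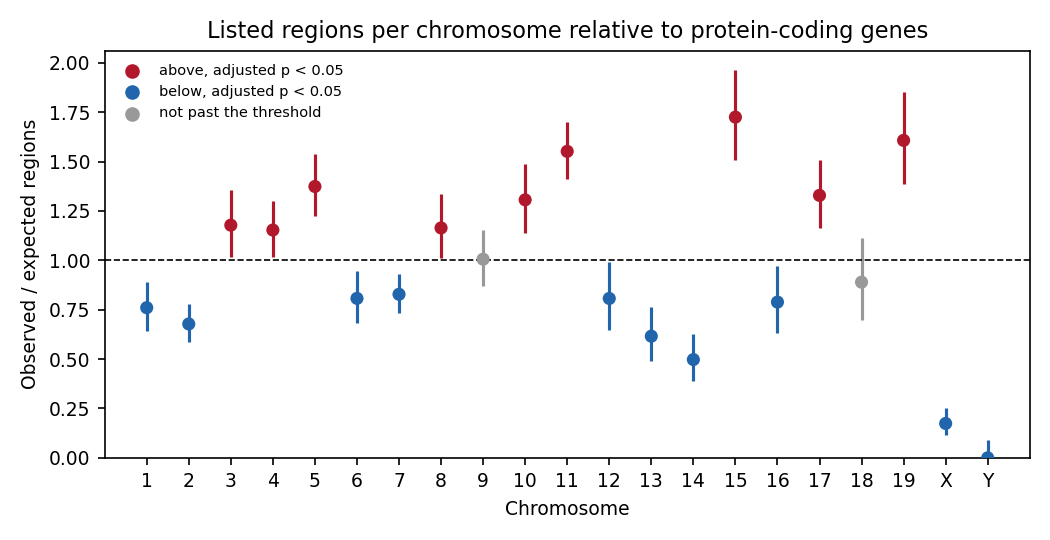
Observed over expected regions (y axis) for each chromosome (x axis), where the expectation is the chromosome's share of protein-coding genes. Points are ratios, bars are 95% exact binomial intervals and the dashed line is a ratio of 1. Chromosomes 11, 15 and 19 lie highest, at 1.55, 1.72 and 1.61, and chromosome X lies at 0.174.

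Within chromosomes a minority of the regions was gathered into short stretches, while 2466 of the 3516 had no other region within 10 kb. The window of 1 Mb with the most regions, from 5 to 6 Mb on chromosome 19, held 32, and 2 adjoining windows on chromosome 10, from 79 to 80 Mb and from 80 to 81 Mb, held 25 and 29. Further dense windows lay on chromosome 15 from 76 to 77 Mb with 25 regions, chromosome 7 from 18 to 19 Mb with 22, and chromosome 11 from 97 to 98 Mb and 98 to 99 Mb with 20 and 18. Windows starting at 34 and 35 Mb on chromosome 17 held 17 and 16 regions. The average density was 1.29 regions per Mb, and the densest window in any of 1000 random placements on the same chromosomes held 13 (one-sided permutation test by random placement, p = 0.001, the smallest that 1000 placements can give). In the list 18 windows exceeded that value, and these contained 333 regions, 9.47% of the total. When regions less than 340 bp apart were joined into one interval, 10 windows, with 187 intervals (5.88%), exceeded the random maximum, which was again 13. The window on chromosome 19 then held 29 intervals, those on chromosome 10 held 23 and 25, and those on chromosomes 15 and 7 held 20 and 19. On chromosome 11 the windows at 97 and 98 Mb fell to 12 and 15 and on chromosome 17 those at 34 and 35 Mb fell to 14 and 11, so that the first on chromosome 11 and the second on chromosome 17 no longer exceeded random placement. The windows were chosen after their values were seen. Positions in these placements were uniform along each chromosome, so gene density within a chromosome was not taken into account. Whether the dense windows hold more regions than their genes would give was not tested.

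**Figure D3:**
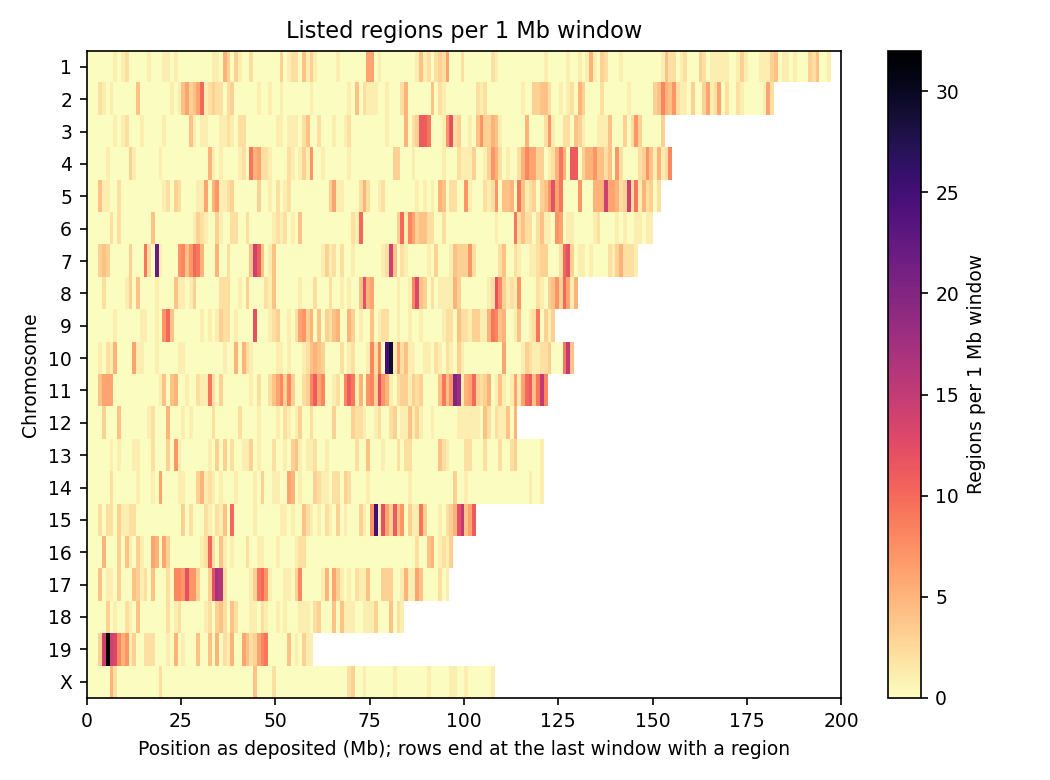
Number of regions per 1 Mb window (colour) along each chromosome (rows), with position as deposited in Mb on the x axis. The darkest windows are 5 to 6 Mb on chromosome 19 with 32 regions, 79 to 81 Mb on chromosome 10 with 25 and 29, and 76 to 77 Mb on chromosome 15 with 25. Chromosome X is sparsely filled, with 27 regions in all.

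At a finer scale, 1050 regions (29.9%) had another listed region within 10 kb. Random placement of the same regions on the same chromosomes gave 134 ± 16.0 (SD over 1000 placements, highest 192), so the observed number was 7.86 times the random mean (one-sided permutation test by random placement, p = 0.001). When each region was instead moved by up to 1 Mb, which keeps only density that varies over several Mb, the random mean was 320 and the ratio 3.28 (permutation p = 0.001). Placing each region within its own window of 1 Mb, which keeps the count of every window, gave a random mean of 378 and a ratio of 2.78 (permutation p = 0.001). Linked in this way, the regions formed 2466 single regions and 466 groups of 2 or more. The group with most members, 6 regions, lay on chromosome 15 from 76022301 to 76035560, covered 8470 bp and included the third widest region of the list. Groups of 5 regions lay on chromosome 4 from 129670272 to 129679151, chromosome 7 from 28080072 to 28092160 and chromosome 10 from 12557901 to 12569670 and from 79541981 to 79572240. They were the next named groups, taken in genomic order from the 7 groups of 5.

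Most of this proximity consisted of regions separated by a small gap, nearly always of the same size. Among the 1050 regions with another within 10 kb, 657 had one less than 340 bp away. Of the 338 pairs of neighbours less than 340 bp apart, 332 were exactly 10 bp apart. Joining regions less than 340 bp apart, an alternative chosen after seeing the data, reduced the list to 3178 intervals, of which 319 combined 2 or more regions, and raised the median width to 970 bp. After joining, 459 intervals (14.4%) had a neighbour within 10 kb, against 109 ± 14.3 in random placements, a ratio of 4.21 (permutation p = 0.001). The same count was 1.79 times the mean of placements moved by up to 1 Mb and 1.55 times the mean of placements within the same 1 Mb window (permutation p = 0.001 for each). The group of 6 on chromosome 15 then comprised 3 intervals, and the 5-member groups on chromosomes 4 and 7 also comprised 3 each. On chromosome 10 the group at 12557901 comprised 2 intervals and that at 79541981 comprised 4.

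**Figure D4:**
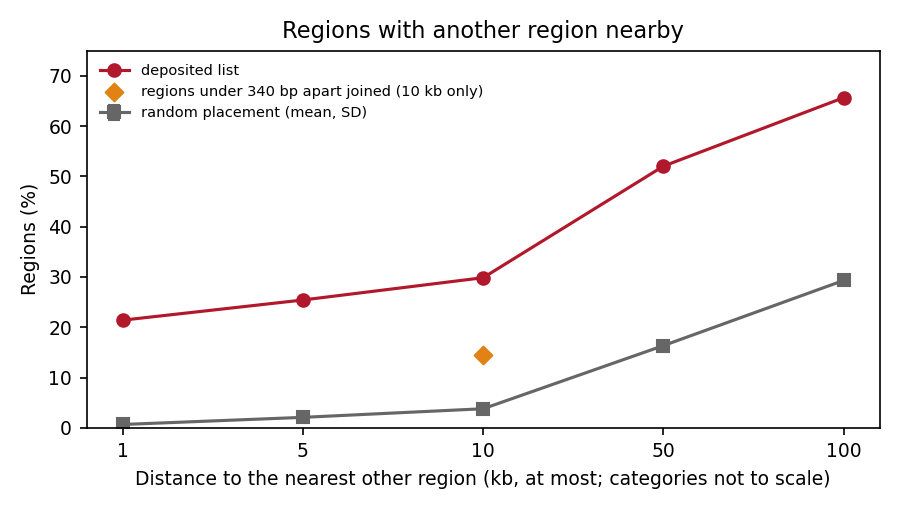
Percentage of regions (y axis) with another region within 1, 5, 10, 50 or 100 kb (x axis, categories). Red circles are the deposited list, grey squares the mean of 1000 random placements with SD bars, and the orange diamond the list after joining regions less than 340 bp apart, at 10 kb. The deposited list lies above random placement at each distance, at 29.9% against 3.80% for 10 kb, and the joined list lies at 14.4%.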

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

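The uneven distribution over chromosomes and the proximity of regions kept their direction and their side of the threshold under all alternatives run. The chi-square ranged from 357 (autosomes only) to 1249 (chromosome length), and 14 to 20 chromosomes passed. The ratio on chromosome 11 ranged from 1.43 to 2.55 and on chromosome X from 0.123 to 0.193. For the deposited list at 10 kb, proximity was between 2.78 and 7.86 times its random mean, depending on the placement. Other settings measured something different. The lowest ratio was 1.55, for joined intervals placed within their 1 Mb windows. The highest was 32.1, for neighbours within 1 kb in the deposited list, which includes the pairs less than 340 bp apart. Against chromosome length the ratio on chromosome 7 reversed to 1.44, past the threshold, and on chromosome 3 it turned to 0.901 and did not pass; the cause was not tested. Of 165 single-chromosome alternatives, 140 kept their side of the threshold and 3 gained a call; 20 lost the call with the direction kept, and the other 2 are those named here. Joining regions less than 340 bp apart lowered the number of 1 Mb windows above random placement from 18 to 10. The median width moved to 980 bp with regions within 1 kb merged, to 970 bp with regions under 340 bp apart joined and, by construction, to 1020 bp among the 1759 regions of at least the median width. No paired analysis was possible because the list holds no values per library, and for the same reason no replicate could be left out. Depth, and whether any region was also enriched in the BirA-only line, could not be examined.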

Other observations

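The tests in this part were chosen after the data were seen, apart from the comparisons of chromosome X with length, with all annotated genes and with protein-coding genes.

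The first pattern concerns the boundaries of the regions: 2230 starts (63.4%) and 2324 ends (66.1%) lay on a grid of 340 bp, where 0.294% would fall by chance, while the 1286 other starts all lay at a multiple of 10 plus 2. Both boundaries were on the 340 bp grid in 1457 regions, 1 boundary in 1640 and neither in 419. A candidate explanation is an overlap of intervals on 2 grids, as from intersecting a pair of call sets. All 155 regions under 340 bp (100%) had exactly 1 boundary on the 340 bp grid, against 78.0% of the 1904 longer regions not wholly on it (Fisher's exact test, 2-sided, p = 1.65e-16), as slivers of overlap would. Regions this short cannot have both boundaries on that grid. Whether intervals with neither boundary on it can be so short is not known. The width cut alone could therefore produce the difference, and the comparison gives limited support. The widths, including the regions of 1 bp, may then describe the grids more than the extent of Klf9 association; no biological explanation was tested.

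The second pattern is the closeness of neighbouring regions. One interval listed in pieces stays open for the closest pairs, where 332 of 338 gaps under 340 bp were exactly 10 bp, a regularity that prompted the idea and so does not test it. At all 338 gaps both flanking boundaries lay off the 340 bp grid, while 63.4% of all starts and 66.1% of all ends lay on it. Gaps this short cannot have both boundaries on that grid, but could have 1. This was seen in the same gaps and does not test the idea either. Pieces less than 340 bp apart do not account for the rest of the closeness. After joining, 459 intervals still had a neighbour within 10 kb, above the highest of 1000 random placements (155). Pieces with wider gaps were not joined in that count. A further 60 gaps measured 340 bp to under 1 kb, and for these the explanation stays open. Regional density over several Mb falls short as the whole cause, since the joined count was 1.79 times the mean of placements moved by up to 1 Mb (highest 330), and so does regional density at the scale of 1 Mb, since it was 1.55 times the mean of placements within the same 1 Mb window (highest 371). Pieces with wider gaps could contribute to both ratios. Density that varies within a window, as between neighbouring genes, remains open and was not tested.

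The third pattern is the scarcity of regions on chromosome X. Fewer genes or less length on chromosome X would bring the ratio to about 1, but it was at most 0.164 against length, all annotated genes or protein-coding genes without receptors. A lower copy number of chromosome X in these cells cannot be told apart from weaker association: the upper 95% bound of the ratio, 0.253, is known only for called regions, which need not scale with copy number, and no input signal was analysed here. Filtering of repeated sequence by the authors also stays open, untested.

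A further hypothesis is that the regions lie at gene boundaries. The midpoints on each chromosome were shifted by a constant of up to 5 Mb against the GRCm38 gene table. At the best shifts 791 of 3516 (22.5%) came within 500 bp of a protein-coding gene boundary, compared with 175 at no shift. The median counts over all shifts, summed over chromosomes, came to 83. The best shift was chosen for each chromosome by its count, so the 791 include matches gained by that choice. In 100 lists whose groups of regions were moved by up to 1 Mb, the best shifts gave at most 342. The highest count exceeded that of each randomised list on 19 of 20 chromosomes, chromosome X (6 of 27 regions) being the exception. On chromosome 11 it was 160 of 401 regions at a shift of 184 kb, where the median shift gave 13. The best shift was not 0 on 19 chromosomes, which argues against positions given on GRCm38. Chromosome X adds nothing to this, since its highest count of 6 was below the 7 reached in randomised lists. On chromosome 19 the best shift was 0, and 40 of 182 regions matched. The excess over the randomised lists points to a part of the list near ends of genes, of a size not estimated here. It cannot separate start sites from gene ends, rests on 1 constant shift per chromosome, and names no gene.

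The regions are not listed in genomic order, and the basis of the order is not given in the sources used here. Over 10 successive parts of equal size the median width rose from 824 bp in the first to 999 bp in the sixth and was 830 bp in the last (permutation test over the 10 parts, p = 1e-05, the smallest that 100000 permutations can give). The order therefore carries some information on width, and was not used as a rank.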
